A study of Bos taurus with 8 samples.

How the data were processed

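Polyadenylated RNA of single cells from bovine embryos was measured at 4 ages, 6 to 9 days after fertilization. Per the labels' protocols, single cells were lysed, reverse transcribed with an oligo(dT) primer and amplified by PCR with a barcode per cell. The barcoded cDNAs were then pooled, sheared and enriched before adaptors were ligated. A library is therefore a pool of cells, and the labels describe 8 libraries. The 6 wildtype libraries, numbered as replicates 1 to 6 in the labels, were used. The other two, from embryos injected with BE3 base editor RNA with and without SOX2 guides, were not analysed here.

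The submitters' processing notes name Trim Galore, HISAT2, featureCounts and Seurat, with no versions, and the genome build ARS-UCD1.2. The order and settings of these tools, the filters on cells and genes, and whether molecular identifiers were counted are not given in the sources used here. The table deposited by the authors holds natural log values, ln(1 + value per 10000), for 18825 genes in 286 cells. After the log was undone every cell summed to 10000, and 100% of the values in every cell were whole multiples of the smallest step of that cell, within a tolerance of 0.1 reads. Each cell's total of assigned reads was recovered from that step. The authors' cell table lists 288 cells, 2 of which have no column of values, and gives each cell 1 of 7 classes and 1 of 4 ages. How the classes were assigned is not given in the sources used here. The classes were made from these same cells, so genes that define a class are not independent evidence that it differs.

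The abbreviations EB, MB and LB are printed as the cell table gives them. TE, ICM, EPI and PE are the field's usual short forms of trophectoderm, inner cell mass, epiblast and primitive endoderm, which in cattle is mostly called hypoblast. Cells were tied to libraries by the library code in their names. The labels name no embryo and no sex for a cell, so the library was the replicate. No comparison of sexes was run, and sex was not inferred from the values. Nothing says which embryos went into which library, so p-values measure only the spread between libraries, which may be technical.

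Values were put on a per-million scale, printed as CPM, and averaged over the cells of a library and class, or of a library and age, where it held at least 3 such cells. These averages were transformed as log2(value + 10), so log2 changes of genes with low values are understated. Genes were tested if their average reached 10 CPM in at least as many averages as the smallest group held. Linear models were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes, trend and robust options), with statmod 1.5.0 and, for reading files, data.table (1.17.8). The library entered as a random block, because a library gave cells of several classes. Averages from the same library deviated together, with a consensus correlation of 0.291 between ages and 0.18 between classes. A single fit covered all 7 classes (12540 genes tested) and another all 4 ages (11481 genes tested). P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed. Every adjusted p of a gene is from limma, and SE is the standard error of its log2 change. Group levels are means ± SD of the library averages. The tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where the text says otherwise. The comparisons of LB TE with MB TE and of LB EPI with MB ICM were added after the cell table was seen.

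The fixed lists, 24 in number, had 529 members, of which 491 were in the table. They covered epiblast, trophectoderm, hypoblast, oocyte, epithelial junction, Hippo, FGF and ERK, Nodal, BMP and WNT, epigenetic, glycolysis, oxidative phosphorylation, ribosomal protein, lipid and sterol, cell cycle, p53 and stress, interferon, X inactivation, X-linked housekeeping, genes that escape X inactivation in humans, Y-linked, cumulus and granulosa, sperm, fibroblast and blood genes. No member of the Y-linked list was in the table. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests only whether its members move together. The named genes were, per comparison, up to 10 rises and 10 falls of the largest size among called genes with a symbol that changed the same way in every library holding both groups. Up to 4 members of each list with the smallest adjusted p were added, and SOX2, NANOG, POU5F1, CDX2, GATA3, GATA6, SOX17, KRT18 and XIST always. The text prints a part of these genes.

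A gene table of assembly ARS-UCD2.0, not the authors' build, was used only for names and for membership of the X chromosome, and none of its coordinates were used. It matched 17114 genes by symbol and 257 by an older symbol, 92.3% of the table, and left 1454 unmatched. Of the matched genes 644 were X-linked and 16720 autosomal. Of the gene names 22 looked like calendar dates, and these were left as they stood. The X to autosome ratio was the median of X genes over the median of autosomal genes, each over genes of at least 10 CPM in that library and class. It was compared by two-sided exact permutation tests, and set among 10000 random autosomal sets of the same size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

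Depth was taken from the recovered reads. Library medians ranged from 84897 to 195159 reads per cell, and 22 cells had fewer than 20000. Intervals on shares of cells are 95% Clopper-Pearson intervals and cover the counting of cells only. They leave out any dependence between cells of the same library or embryo. Reads amplified by PCR may not be independent molecules. Intervals on levels pooled over cells are bootstraps of whole cells. Cells were not treated as replicates in tests of genes, and no doublet caller was run.

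The fits were tested on simulated data built from the measured means and depths, with 200 changed genes. The spread was set, not estimated from the data, at an SD of 0.3 between averages and 0.15 between libraries on the log2 scale. The recovery depends on these values. For MB TE against MB ICM, where 11314 genes were tested, 6% of genes with a log2 change of 1 and 56% with a change of 2 were recovered. For LB TE against LB EPI, on the same 11314 genes, the recovery was 2% and 45%. It was 21% and 80% for day 9 against day 8, and 4% and 53% for day 9 against day 6, on 10566 genes. These 4 simulated comparisons gave 0 to 3 false calls, and the 6 that did not hold these changed genes gave 0 calls. The class simulation also raised X genes 1.5-fold in LB EPI. LB PE against LB EPI, LB EPI against MB ICM and the interaction therefore held a change in X genes of which no gene was called. An X-linked change of 1.5-fold came back as 1.21-fold from the ratio of medians, which therefore understates such changes.

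Results were also computed with pseudocounts of 1 and 50, no filter on low values, the mean over cells of log2 values, median-of-ratios scaling, at least 5 cells per average, no library block, and leaving out each library. For the X to autosome ratio the alternatives were thresholds of 1 and 50 CPM, a mean without the top 5% of genes and a single set of genes. For the gene lists they were the estimated correlation and fry, and for shares of cells only cells at or above the median number of genes. Those added after seeing the data were the library as a fixed effect, limma-voom on summed recovered reads, the removal of cells under 20000 or 50000 reads, and the X share of all values.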

Results

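Expression was measured in 286 single cells of bovine embryos collected on days 6, 7, 8 and 9 after fertilization, in 6 wildtype libraries. The day 6 cells were all of the class Morula (58 cells, 20.3% of all cells, 95% interval 15.8 to 25.4) and the day 7 cells of the class EB (39 cells, 13.6%, 9.88 to 18.2). Day 8 held MB ICM (51 cells, 17.8%, 13.6 to 22.8) and MB TE (37 cells, 12.9%, 9.28 to 17.4). Day 9 held LB EPI (45 cells, 15.7%, 11.7 to 20.5), LB PE (25 cells, 8.74%, 5.74 to 12.6) and LB TE (31 cells, 10.8%, 7.48 to 15.0). These shares describe the cells in the table and depend on how cells were picked. Replicates 4 and 6 carried the day 6 and day 7 averages and replicates 1, 2, 3 and 5 those of days 8 and 9, so age and library cannot be told apart across that step.

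The recovered depth was 48628984 reads in all, with a median of 150770.5 reads and 7843 detected genes per cell. Libraries differed, with medians of 152851.5 reads per cell in replicate 1, 195159 in replicate 2, 109997 in replicate 3, 106883.5 in replicate 4, 184334 in replicate 5 and 84897 in replicate 6. LB PE cells were the shallowest class, with a median of 39210 reads, against 196981 in LB EPI and 196521 in LB TE.

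Trophectoderm, the outer epithelium that later forms placenta, and the inner cell mass were compared on day 8. Each class had 3 libraries, of which 2 held both classes. The MB TE averages rested on 21, 12 and 3 cells in replicates 1, 2 and 3. The MB ICM averages rested on 24, 21 and 5 cells in replicates 1, 2 and 5. All averages had the same weight. The largest rises in MB TE were the simple-epithelium keratins. KRT18 stood at 17330 ± 7890 CPM (SD, n = 3) against 643.5 ± 205 in MB ICM (n = 3), a log2 change of 4.46 (SE 0.39, adjusted p = 4.19e-06), and KRT8 rose by 4.25 (SE 0.26, adjusted p = 7.55e-09). CDX2, a transcription factor of trophectoderm, was at 63.4 ± 9.24 CPM in TE and 2.79 ± 1.58 in ICM (log2 change 2.47, SE 0.33, adjusted p = 4.12e-05). The pluripotency factor NANOG was at 15.0 ± 4.12 in TE and 153.9 ± 42.4 in ICM, and fell by 2.61 on the log2 scale (SE 0.34, adjusted p = 2.39e-05). SOX2, also a pluripotency factor, fell by 2.80 (SE 0.47, adjusted p = 0.000591).

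In all, 749 of the 12540 tested genes were higher in MB TE and 515 lower. Of 30 measured trophectoderm genes 18 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 1.51e-32). Besides the keratins these included the endocytic adaptor DAB2, up by 3.72 (SE 0.29), PLAC8, up by 2.96 (SE 0.27), and the transcription factor GATA3, up by 1.74 (SE 0.25, adjusted p = 9.53e-05). Among 27 epithelial junction genes 13 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.44e-12), with EZR, which ties the membrane to actin, up by 2.61 (SE 0.23), the desmosomal cadherin DSC2 up by 3.04 (SE 0.38) and AMOT, an adaptor of the Hippo pathway, up by 2.28 (SE 0.33). The epithelial cytolinker EPPK1 (log2 change 3.49, SE 0.34), the membrane protease PRSS8 (3.38, SE 0.33), the bile acid transporter SLC10A1 (3.11, SE 0.39) and the endocytic receptor LRP2 (3.04, SE 0.32) were also higher. So were DNMT3A, which places new DNA methylation, by 2.51 (SE 0.31, adjusted p = 1.69e-05), TET1, which oxidises it, by 1.44 (SE 0.31, adjusted p = 0.00428), and TEAD3, a DNA-binding partner of YAP, by 1.53 (SE 0.29, adjusted p = 0.00142).

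Genes higher in MB ICM came from both inner lineages. Of 24 hypoblast genes 11 fell and 2 rose in TE (11 and 3 adjusted over the list alone; camera adjusted p = 6.04e-07, adjusted p = 0.0766 with an estimated correlation). Fibronectin, FN1, was at 3438 ± 105 CPM in ICM (n = 3) and 403.1 ± 136 in TE (n = 3), a log2 change of -3.09 (SE 0.25), while the nuclear receptor HNF4A changed by -2.90 (SE 0.29) and the growth factor receptor PDGFRA by -2.85 (SE 0.32, adjusted p = 5.23e-06). On day 9 HNF4A was at 191.8 ± 54.9 CPM in LB EPI and 179.1 ± 6.83 in LB PE, so it did not mark the hypoblast alone. Of 25 epiblast genes 7 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0034), DPPA4 among them with -1.39 (SE 0.29, adjusted p = 0.00265). The adhesion protein FLRT3 changed by -3.51 (SE 0.36), the ETS factor SPIC by -3.24 (SE 0.52), the galectin LGALS4 by -2.89 (SE 0.28), the fatty acid carrier FABP3 by -2.49 (SE 0.37) and the receptor FGFR4 by -2.18 (SE 0.31). GATA6, an early hypoblast factor, did not differ detectably, at 252.4 ± 91.6 in TE and 243.5 ± 87.2 in ICM (log2 change -0.01, adjusted p = 1, turning to 0.42 without replicate 2). POU5F1 fell by 0.98 (SE 0.30, adjusted p = 0.0385), a call lost without replicate 2 (adjusted p = 0.187), 3 (0.128) or 5 (0.111). Of 34 ribosomal protein genes 2 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 5e-07, adjusted p = 0.479 with an estimated correlation). Of 27 cell cycle genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), and the list missed the threshold with camera (adjusted p = 0.0562) and passed it with fry (0.0225). No list of other cell types passed the test in this comparison, with camera adjusted p = 0.668 for cumulus and granulosa, 0.73 for sperm, 0.324 for fibroblast and 0.58 for blood genes. Without replicate 2 the count of called genes was 635 in place of 1264. With at least 5 cells per average, which drops MB TE of replicate 3, the count was 818. With the mean over cells of log2 values 78.7% of called genes were higher in TE, in place of 59.3%.

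**Figure D1:**
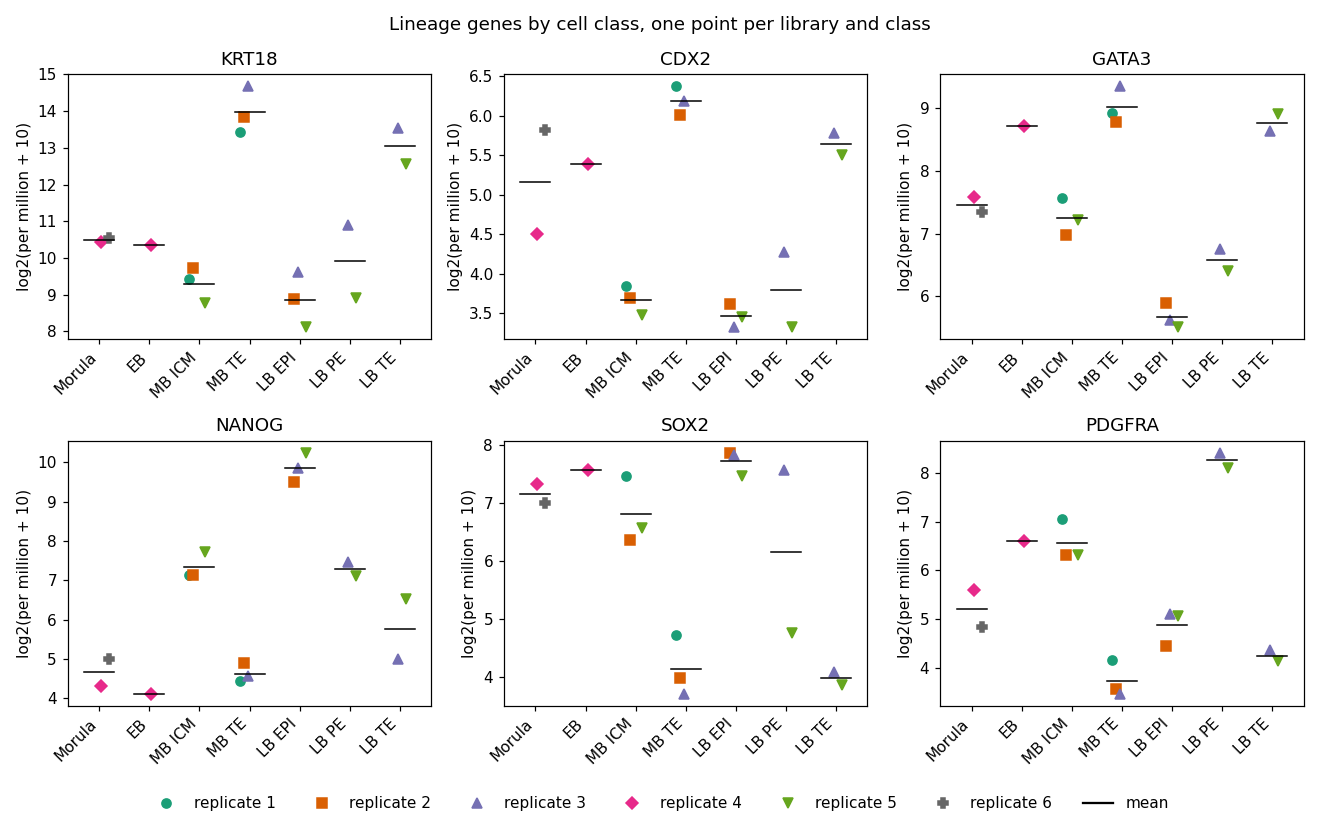
Lineage genes by cell class. Each panel gives 1 gene, with log2(CPM + 10) on the vertical axis and the cell classes on the horizontal axis; each point is the average of 1 library and class, its shape and colour give the replicate, and black lines are means. KRT18, CDX2 and GATA3 are highest in MB TE and LB TE among the day 8 and day 9 classes, NANOG is highest in LB EPI (mean 948.2 CPM) and PDGFRA in LB PE (mean 299 CPM).

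On day 9 the trophectoderm (LB TE, 2 libraries) was compared with the epiblast (LB EPI, 3 libraries), the layer that forms the body of the embryo. KRT8 reached 23300 ± 4440 CPM (SD, n = 2) against 1007 ± 365 (n = 3), a log2 change of 4.55 (SE 0.29, adjusted p = 1.45e-08). The prostaglandin synthase PTGS2 was at 1631 ± 399 against 85.0 ± 34.2 (log2 change 4.11, SE 0.44, adjusted p = 3.79e-06). NANOG was at 52.5 ± 43 in LB TE and 948.2 ± 248 in LB EPI and fell by 4.13 (SE 0.37, adjusted p = 2.99e-07). SOX2 was at 5.77 ± 1.7 against 201.3 ± 31.6 and fell by 3.74 (SE 0.52, adjusted p = 6.8e-05). TDGF1, the co-receptor of Nodal, changed by -4.001 (SE 0.54, adjusted p = 5.54e-05).

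LB TE had 1037 genes higher and 865 lower. Of 30 trophectoderm genes 22 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 6.19e-36), among them KRT18 by 4.20 (SE 0.43), DAB2 by 4.15 (SE 0.32), PLAC8 by 3.93 (SE 0.30), GATA3 by 3.08 (SE 0.28, adjusted p = 3.52e-07) and CDX2 by 2.19 (SE 0.37, adjusted p = 0.000303). Of 27 junction genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 4.87e-14), with the desmosome protein DSP up by 3.30 (SE 0.38), EZR by 2.81 (SE 0.25) and the tight junction claudin CLDN6 by 2.63 (SE 0.24), and the polarity kinase PRKCI down, with a log2 change of -3.18 (SE 0.35). The calcium-binding protein S100A10 rose by 3.86 (SE 0.28) and FXYD4, a regulator of the sodium pump, by 3.81 (SE 0.41). Interferon tau, IFNT3, the signal by which a ruminant embryo maintains pregnancy, rose by 3.92 (SE 0.65, adjusted p = 0.000566) and the pregnancy-associated glycoprotein PAG2 by 3.95 (SE 0.45). Both belong to families of near-identical copies that may share reads, so these values are uncertain for the single gene. Of 27 lipid and sterol genes 8 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.000209, adjusted p = 0.494 with an estimated correlation), such as HMGCS1 of the cholesterol pathway, up by 2.50 (SE 0.49, adjusted p = 0.00186).

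The epiblast list fell as a group in LB TE, with 12 of 25 genes down and 0 up (12 and 0 adjusted over the list alone; camera adjusted p = 2.89e-09), POU5F1 by -2.75 (SE 0.33, adjusted p = 7.83e-06). Of 19 Nodal, BMP and WNT genes 7 fell and 0 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.000713), as did 4 of 17 FGF and ERK genes, with 1 up (6 and 1 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.167 with an estimated correlation). The ligand GDF3 changed by -2.68 (SE 0.41) and DUSP6, a feedback phosphatase of ERK, by -1.43 (SE 0.35, adjusted p = 0.00665). Of 27 cell cycle genes 7 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.000329), with the topoisomerase TOP2A at 351.3 ± 165 against 2460 ± 573 CPM (log2 change -2.90, SE 0.33) and the replication helicase subunit MCM5 at -1.30 (SE 0.27, adjusted p = 0.00166). Of 23 epigenetic genes 6 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.338 with an estimated correlation), including the Polycomb partner JARID2 at -3.26 (SE 0.47), the histone demethylase KDM4A at -2.88 (SE 0.38) and the deacetylase HDAC8 at -2.30 (SE 0.34). LRRC3 (-3.68, SE 0.38), the ubiquitin-like ligase HERC5 (-3.98, SE 0.42) and the Ras family member ERAS (-3.80, SE 0.43) were also lower in LB TE. GATA6 was higher by 1.37 (SE 0.37, adjusted p = 0.0129), a call lost without replicate 3 (adjusted p = 0.118). Ribosomal protein genes fell in 1 of 34 and rose in 0 (0 either way adjusted over the list alone; camera adjusted p = 0.00675, adjusted p = 0.72 with an estimated correlation). Without replicate 3 the count of called genes was 851 in place of 1902, and without replicate 5 it was 1040.

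The day 8 and day 9 trophectoderm comparisons called many genes in common. Of the genes tested in both, 492 were higher in TE on both days, where independent lists would share 61.9, and 210 were lower on both, against 35.5. Genes called in opposite directions numbered 1 and 3. The compared cells came partly from the same libraries and the classes were named on these cells, so the excess is not a measure of a shared effect.

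The day 9 primitive endoderm (LB PE, 2 libraries), the layer that lines the yolk sac, was compared with LB EPI. PDGFRA was at 299 ± 48.4 CPM (SD, n = 2) against 19.9 ± 7.11 (n = 3), a log2 change of 3.36 (SE 0.36, adjusted p = 7.96e-06). RSPO3, which strengthens WNT signals, rose by 3.78 (SE 0.37, adjusted p = 3.26e-06) and FN1, at 4593 ± 170 against 604.7 ± 162, by 2.96 (SE 0.28, adjusted p = 2.1e-06). GATA6 was at 396.1 ± 193 against 42.4 ± 15.3 and rose by 2.87 (SE 0.37, adjusted p = 5.66e-05). SOX17, also of the hypoblast list, was at 0 CPM in LB PE and in LB EPI and was not tested. NANOG was at 148 ± 27.7 in LB PE and fell by 2.61 (SE 0.37, adjusted p = 0.000218).

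Here 374 genes were higher and 302 lower in LB PE. Of 24 hypoblast genes 11 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.11e-20). The glutamate transporter SLC1A3 (log2 change 3.83, SE 0.37), the adhesion protein MPZL2 (3.74, SE 0.31), the folate receptor FOLR1 (3.67, SE 0.32), the FGF co-receptor KLB (3.41, SE 0.34) and clusterin, CLU (3.37, SE 0.47), were higher as well. Of 27 junction genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.15e-05), such as the tight junction protein CGN at 2.56 (SE 0.45, adjusted p = 0.00163), a call lost without replicate 3 (adjusted p = 0.0734). Trophectoderm genes moved the same way, 5 up and 1 down of 30 (8 and 1 adjusted over the list alone; camera adjusted p = 1.15e-05, adjusted p = 0.122 with an estimated correlation). GATA3 (log2 change 0.89, adjusted p = 0.0717) and CDX2 (0.35, adjusted p = 0.698) did not pass the test, and the CDX2 value turned to -0.18 without replicate 3. Of 25 epiblast genes 6 fell and 2 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.00402), KLF17 by -2.01 (SE 0.34, adjusted p = 0.00111) among the falls and DPPA3 by 1.86 (SE 0.39, adjusted p = 0.00689) among the rises, the latter lost without replicate 5 (adjusted p = 0.0888). LRRC3 changed by -3.47 (SE 0.38), the phosphatase subunit PPP2R2B by -3.26 (SE 0.37), ERAS by -3.23 (SE 0.43), the growth factor carrier IGFBP3 by -2.86 (SE 0.39) and midkine, MDK, by -2.70 (SE 0.32). SOX2 was at 97.9 ± 114 in LB PE against 201.3 ± 31.6, and its log2 change of -1.55 did not pass the test (adjusted p = 0.0948). Without replicate 3, which leaves 1 LB PE average, the SOX2 change was -2.90. POU5F1 fell by 1.14 (adjusted p = 0.0479), and its call was lost without replicate 1 (adjusted p = 0.0544), 2 (0.195), 3 (0.0775), 4 (0.0618), 5 (0.163) or 6 (0.0559).

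In LB PE, whose cells had a median of 39210 reads, the fibroblast list stood higher with camera, although 0 of its 11 measured genes was called by limma, over all genes or over the list alone (camera adjusted p = 0.00673, adjusted p = 0.763 with an estimated correlation, fry adjusted p = 0.368). Called genes fell to 408 from 676 without replicate 2 and to 260 without replicate 5. Without the library block the count was 387. The share of called genes that were higher in LB PE, 55.3%, was 78.8% without replicate 5, 70.5% of 414 with limma-voom and 24.5% of 994 with the mean over cells of log2 values.

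LB PE was also set against LB TE, 2 libraries each, both holding both classes. FN1 was at 4593 ± 170 CPM (SD, n = 2) against 244.1 ± 54.5 (n = 2), a log2 change of 4.20 (SE 0.30, adjusted p = 3.9e-08), and PDGFRA rose by 4.01 (SE 0.38, adjusted p = 4.81e-06). The basement membrane genes NID1 (3.88, SE 0.60) and COL4A1 (3.37, SE 0.57), RSPO3 (3.81, SE 0.40) and FLRT3 (3.67, SE 0.43) were higher too. KRT8 was at 2513 ± 1510 in LB PE and fell by 3.34 (SE 0.31, adjusted p = 4.81e-06). DAB2 changed by -3.32 (SE 0.35), PTGS2 by -3.24 (SE 0.47), KRT18 by -3.15 (SE 0.46) and GATA3 by -2.19 (SE 0.31, adjusted p = 0.000161).

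The comparison called 309 genes higher and 425 lower in LB PE. Of 24 hypoblast genes 14 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.13e-24), and of 30 trophectoderm genes 15 fell and 0 rose (20 and 2 adjusted over the list alone; camera adjusted p = 5.22e-25). Junction genes fell more often than they rose, 8 against 1 of 27 (9 and 1 adjusted over the list alone; camera adjusted p = 1.15e-05). Epiblast genes were up in 4 of 25 and down in 0 (9 and 1 adjusted over the list alone; camera adjusted p = 8.03e-05), and FGF and ERK genes in 4 of 17 and 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.000267). Among epigenetic genes HDAC8 was higher in LB PE by 2.24 (SE 0.37, adjusted p = 0.000806). Of the fibroblast list 1 of 11 genes rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.04e-05, adjusted p = 0.263 with an estimated correlation). The calls of several lineage genes were lost when 1 library was left out. GATA6 rose by 1.51 (adjusted p = 0.0238, but a log2 change of 0.95 and 0.402 without replicate 3), SOX2 by 2.18 (0.025, but a log2 change of 0.89 and 0.377 without replicate 3 and 0.0564 without replicate 2) and NANOG by 1.52 (0.0263, but a log2 change of 0.57 and 0.59 without replicate 3 and 0.0515 without replicate 2). CDX2 fell by 1.84 (adjusted p = 0.00695, but a log2 change of -1.51 and 0.185 without replicate 5). Without replicate 5 the count of called genes was 168 in place of 734, and without the library block it was 439. The share of called genes that were higher in LB PE, 42.1%, was 72% without replicate 5 and 17.6% of 1246 with the mean over cells of log2 values. Its majority direction thus depended on the fit.

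LB EPI was also compared with MB ICM, 3 libraries each, of which 2 held both. MB ICM held genes of both inner lineages and LB EPI is only 1 of them, so a change in the mix of cells is not separated here from a change within cells. TDGF1 was at 738.4 ± 18.2 CPM (SD, n = 3) in LB EPI and 33.3 ± 26.2 (n = 3) in MB ICM, a log2 change of 4.23 (SE 0.49, adjusted p = 6.66e-05). NANOG rose from 153.9 ± 42.4 to 948.2 ± 248, by 2.55 (SE 0.34, adjusted p = 0.000144). SOX2 (0.94, SE 0.47, adjusted p = 0.324) and POU5F1 (0.32, SE 0.30, adjusted p = 0.682) did not pass the test. GATA6 was at 42.4 ± 15.3 in LB EPI and 243.5 ± 87.2 in MB ICM and fell by 2.23 (SE 0.33, adjusted p = 0.00036).

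LB EPI had 413 genes higher and 227 lower. LRRC3 rose by 4.21 (SE 0.34, adjusted p = 5.26e-07), the uridine phosphorylase UPP1 by 3.69 (SE 0.64), ERAS by 3.43 (SE 0.39), the costimulatory ligand ICOSLG by 3.41 (SE 0.38) and the forkhead factor FOXO1 by 3.15 (SE 0.51). Of 25 epiblast genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000843), and of 19 Nodal, BMP and WNT genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00193, adjusted p = 0.0647 with an estimated correlation). Among epigenetic genes DNMT3A rose by 1.66 (SE 0.31, adjusted p = 0.00256) and KDM4A by 2.16 (SE 0.35, adjusted p = 0.000685). Of 24 hypoblast genes 6 fell and 0 rose (8 and 1 adjusted over the list alone; camera adjusted p = 3.12e-05, adjusted p = 0.167 with an estimated correlation). MPZL2 changed by -3.19 (SE 0.28), SLC1A3 by -3.01 (SE 0.33), the iron reductase STEAP3 by -2.97 (SE 0.42), FOLR1 by -2.89 (SE 0.29), the glutaredoxin GLRX by -2.81 (SE 0.33), the ectoenzyme CD38 by -2.56 (SE 0.40), FLRT3 by -2.53 (SE 0.36) and GATA3 by -1.57 (SE 0.26).

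Few genes of the energy metabolism lists were called in this comparison. Of 26 oxidative phosphorylation genes 3 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 8.36e-07, adjusted p = 0.348 with an estimated correlation), with the ATP synthase subunit ATP5MC1 at -1.31 (SE 0.28, adjusted p = 0.006), a call lost without replicate 3 (adjusted p = 0.0646) or 5 (0.0853). Of 18 glycolysis genes 2 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00217, adjusted p = 0.514 with an estimated correlation), with the mutase PGAM1 up by 1.32 (SE 0.23, adjusted p = 0.00136). The other, PKM, was up by 0.92 (SE 0.24, adjusted p = 0.0282), a call lost without replicate 1 (adjusted p = 0.104), 2 (0.0933), 3 (0.147) or 5 (0.0796). The count of called genes, 640, was 370 without replicate 1, 325 without replicate 2, 341 without replicate 3 and 315 without replicate 5, and 401 with the library as a fixed effect. With the mean over cells of log2 values 83.9% of called genes were higher in LB EPI, in place of 64.5%.

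Few genes were called between the trophectoderm classes of the days. LB TE against MB TE (2 against 3 libraries, 1 holding both) gave 20 genes higher and 4 lower. MOGAT1, an enzyme of triglyceride synthesis, was at 112.9 ± 27.4 CPM (SD, n = 2) against 9.60 ± 5.83 (n = 3) and rose by 2.71 (SE 0.36, adjusted p = 0.000774, but 0.0746 without replicate 3 and 0.0568 without replicate 5). PPP1R14A, an inhibitor of myosin phosphatase, fell by 2.10 (SE 0.32, adjusted p = 0.00322, but 0.205 without replicate 3 and 0.114 without replicate 5). TKDP1, of the trophoblast Kunitz proteins, rose by 2.59 (SE 0.39, adjusted p = 0.00322, but 0.205 without replicate 3 and 0.0626 without replicate 5), and its near-identical family copies may share its reads. GATA3 (-0.24, turning to 0.13 without replicate 3) and CDX2 (-0.49) did not pass the test, each with an adjusted p = 1. The trophectoderm list stood higher with 0 of 30 genes called (6 up and 2 down adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.711 with an estimated correlation), as did ribosomal protein genes with 0 of 34 called by limma, over all genes or over the list alone (camera adjusted p = 0.00116, adjusted p = 0.711 with an estimated correlation). The 24 calls became 7 without replicate 1, 4 without replicate 3, 13 without replicate 4, 3 without replicate 5 and 11 without replicate 6. They were 11 without the library block and 4 with the library as a fixed effect. Whether trophectoderm and inner cells changed by different amounts is tested next.

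The TE minus inner cell difference was compared between day 9 and day 8 by an interaction term, on 5 and 6 averages. The inner cells were LB EPI on day 9, with LB PE left out, and the undivided MB ICM on day 8. The MB TE average of replicate 3 rested on 3 cells and the MB ICM average of replicate 5 on 5. With at least 5 cells per average 13 genes were called in place of 46. LRRC3 (log2 difference -3.91, SE 0.51, adjusted p = 0.000972), ERAS (-3.78, SE 0.58) and TDGF1 (-3.56, SE 0.73, adjusted p = 0.0385) had a lower difference on day 9. The serine synthesis enzyme PHGDH (3.66, SE 0.66), the amino acid transporter SLC6A20 (3.31, SE 0.48), MPZL2 (2.95, SE 0.42) and FOLR1 (2.87, SE 0.43) had a higher one. MPZL2 and FOLR1 were lower in LB EPI than in MB ICM (-3.19 and -2.89) and higher in LB PE than in LB EPI (3.74 and 3.67), so their interaction is not by itself a change in TE. LRRC3, ERAS and TDGF1 were higher in LB EPI than in MB ICM (4.21, 3.43 and 4.23). They were not called lower in LB TE than in MB TE, so their interaction is not by itself a change in TE either. In all 27 genes had a positive and 19 a negative interaction. Neither NANOG (-1.52, adjusted p = 0.231) nor CDX2 (-0.28, adjusted p = 0.933) nor KRT18 (-0.26, adjusted p = 0.952) passed the test. The epiblast list had 1 of 25 genes down and 0 up (5 and 0 adjusted over the list alone; camera adjusted p = 0.000109). Hypoblast genes were up in 2 of 24 and down in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00181, adjusted p = 0.345 with an estimated correlation), and trophectoderm genes in 0 of 30 either way (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.345 with an estimated correlation). Without replicate 3, the only library with averages of TE on both days, limma called 0 genes (770 at an unadjusted p under 0.05) and KRT18 turned to 0.0047. The log2 differences of the named genes kept their signs there, at 3.16 for MPZL2 (adjusted p = 0.0562), 2.79 for FOLR1 (0.0562), -2.95 for LRRC3 (0.0593), 3.58 for SLC6A20 (0.0657), 3.38 for PHGDH (0.103), -2.94 for ERAS (0.308) and -2.43 for TDGF1 (0.613). Calls were also lost for PHGDH without replicate 1 (adjusted p = 0.134) or 5 (0.0564), and for MPZL2 without replicate 5 (0.0564). They were also lost for FOLR1 (0.0663) and SLC6A20 (0.0544) without replicate 2, and for TDGF1 without replicate 2 (0.0997), 4 (0.0545) or 5 (0.0982). The 46 calls became 11 without replicate 1, 13 without replicate 2, 10 without replicate 5 and 13 without the library block. The share of called genes with a positive interaction, 58.7%, was 38.5% without replicate 2, 40% without replicate 5 and 30.3% of 155 with the mean over cells of log2 values.

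Ages were then compared over all cells of a library, whatever their class. Their averages follow the class mix, since TE made up between 16.7% and 75% of the day 8 cells of a library and EPI between 20.5% and 78.6% of the day 9 cells in the 3 libraries averaged. From day 6 to day 9 (2 and 3 libraries) the keratin KRT19 rose from 20.5 ± 1.21 CPM (SD, n = 2) to 1626 ± 1150 (n = 3), a log2 change of 5.47 (SE 0.65, adjusted p = 0.00124). TDGF1 rose by 5.06 (SE 0.60, adjusted p = 8e-04), UPP1 by 5.21 (SE 0.73), NANOG by 4.25 (SE 0.55, adjusted p = 0.00143) and the apolipoprotein APOA1 by 4.57 (SE 0.67). The homeobox genes ARGFX and DUXA, known from early cleavage embryos, fell by 4.48 (SE 0.41, adjusted p = 4.98e-05) and by 3.25 (SE 0.44), the connexin GJB5 changed by -4.42 (SE 0.55) and GCSH of the glycine cleavage system by -3.04 (SE 0.31). The globin HBG, whose family members resemble each other closely and may share reads, was at 1056 ± 860 on day 6 and 0.774 ± 0.58 on day 9 (log2 change -6.34, SE 0.45, adjusted p = 8.19e-06).

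Day 9 had 249 genes higher and 286 lower than day 6. Of 18 glycolysis genes 7 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 8.7e-10), with ENO1 up by 3.94 (SE 0.42), TPI1 by 3.60 (SE 0.57) and PKM by 3.24 (SE 0.27, adjusted p = 2.6e-05). Of 13 FGF and ERK genes 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.000313). Ribosomal protein genes rose in 1 of 34 and fell in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 8.7e-10, adjusted p = 0.545 with an estimated correlation). The oocyte list stood lower on day 9 with 0 of 18 genes called by limma, over all genes or over the list alone (camera adjusted p = 0.00762, adjusted p = 0.545 with an estimated correlation). Its day 6 level was uneven, since the 18 morula cells of replicate 6 with fewer than 50000 reads held 5793 CPM of oocyte transcripts against 120.3 in the 17 with at least 200000, and 4 of the 18 cells held 82.3% of these reads. The 535 calls became 185 without replicate 2, 813 without replicate 4 and 130 without replicate 6, and 1021 without cells under 50000 reads. Day 9 was higher in 46.5% of the calls, but in 61.1% without replicate 2 and 21.4% without replicate 4.

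Between days 8 and 9 (4 and 3 libraries) 105 genes rose and 25 fell. TDGF1 went from 29.3 ± 18.3 CPM (SD, n = 4) to 415.4 ± 204 (n = 3) and rose by 3.35 (SE 0.43, adjusted p = 0.00335), LRRC3 by 3.09 (SE 0.27, adjusted p = 0.000147) and HERC5 by 2.61 (SE 0.34, adjusted p = 0.00233). STEAP3 changed by -2.01 (SE 0.25, adjusted p = 0.00233). NANOG rose by 2.48 (SE 0.40, adjusted p = 0.0132), a call lost without replicate 2 (adjusted p = 0.0929). KRT18 (-1.32, adjusted p = 0.382), GATA3 (-0.99, adjusted p = 0.224) and GATA6 (-1.04, adjusted p = 0.241) did not pass the test. Of 23 epiblast genes 2 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00706), and of 18 Nodal, BMP and WNT genes 2 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00162). Oxidative phosphorylation genes stood lower with 0 of 26 called (0 up and 1 down adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.408 with an estimated correlation). The 130 calls became 54 without replicate 1, 22 without replicate 2, 25 without replicate 3, 54 without replicate 4 and 51 without replicate 5. They became 18 without the library block, and with the library as a fixed effect limma called 0 genes (1145 at an unadjusted p under 0.05; limma-voom 929).

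The earlier steps rest on few libraries. Day 7 had 1 average against 2 on day 6, and the lone average is assumed to vary like the others. Only 2 genes rose and 0 fell, LOC112448447 by 2.99 (SE 0.35, adjusted p = 0.00555) and LOC112449616 by 2.46 (SE 0.34, adjusted p = 0.0211), both named here after their values were seen. SOX2 (0.36), GATA3 (1.22) and GATA6 (0.73) did not pass the test, with adjusted p = 0.945, 0.808 and 0.915. The count was 1 without replicate 1 or 5, 0 without replicate 2 or 3 (641 and 653 at an unadjusted p under 0.05), 3 without replicate 6, 1 without the library block and 0 with the library as a fixed effect (553 at an unadjusted p under 0.05; limma-voom 41). Epigenetic genes stood higher on day 7 with 0 of 22 called by limma (1 up and 0 down adjusted over the list alone; camera adjusted p = 0.00757, adjusted p = 0.0161 with an estimated correlation, fry adjusted p = 0.193). The oocyte list stood lower on day 7 with 0 of 18 genes called by limma, over all genes or over the list alone (camera adjusted p = 0.0028, adjusted p = 0.692 with an estimated correlation). From day 7 to day 8 (1 and 4 libraries, none shared) 1 gene rose and 7 fell. The LIM protein CRIP1 rose by 3.16 (SE 0.42, adjusted p = 0.0103), BRB, a ribonuclease with close relatives that may share reads, fell by 3.53 (SE 0.47, adjusted p = 0.0103), and the nuclear envelope protein SYNE2 fell by 2.95 (SE 0.42, adjusted p = 0.0108). The trophectoderm list stood higher on day 8 with 0 of 30 genes called (3 up and 0 down adjusted over the list alone; camera adjusted p = 4.22e-07, adjusted p = 0.457 with an estimated correlation). Epigenetic genes stood lower on day 8 with 0 of 22 called by limma, over all genes or over the list alone (camera adjusted p = 0.0376, adjusted p = 0.125 with an estimated correlation). The median of all genes shifted by -0.14 in this step with the deposited scaling and by -0.013 with median-of-ratios scaling. The 8 calls became 0 without replicate 2 (639 at an unadjusted p under 0.05), where CRIP1 (adjusted p = 0.0722), BRB (0.08) and SYNE2 (0.08) were lost, 5 without replicate 3 and 4 without replicate 5.

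The series title names dosage compensation of the X chromosome, so X-linked genes were compared with autosomal genes. A ratio near 1 means that expressed X genes were about as high as expressed autosomal genes. It was 1.11 ± 0.0546 in LB EPI (SD, n = 3), 0.977 ± 0.0799 in LB TE (n = 2) and 0.913 ± 0.129 in LB PE (n = 2). On day 8 it was 1.09 ± 0.188 in MB ICM (n = 3) and 0.946 ± 0.103 in MB TE (n = 3). It was 1.001 ± 0.144 in Morula (n = 2) and 1.04 in the single EB average. These levels hold for the threshold of 10 CPM. With a threshold of 1 CPM every average was below 1, from 0.5797 in MB ICM of replicate 1 to 0.9543 in MB ICM of replicate 5. In the plot of X genes by class, MB ICM of replicate 2 stood highest, with a ratio of 1.31 that lay at the 99.8th percentile of random autosomal sets. Replicate 3 held the lowest ratios, 0.8214 in LB PE (percentile 2.07) and 0.8304 in MB TE (percentile 2.02). These were picked as the extremes of all averages.

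Two-sided exact permutation tests of this ratio had few averages to work with and ignored the pairing of classes within libraries. The smallest p they could give was 0.0286 for day 9 against day 8, 0.333 for LB PE against LB TE and 0.1 for all others, so no p under 0.05 was possible except for day 9 against day 8. LB TE against LB EPI and LB PE against LB EPI each gave the smallest possible exact p = 0.1, and 0.4 after adjustment over the 8 comparisons. MB TE against MB ICM gave exact p = 0.5, with 0.979 against 0.972 in replicate 1 and 1.03 against 1.31 in replicate 2. Within libraries LB TE was below LB EPI in both (0.92 against 1.07 in replicate 3 and 1.03 against 1.09 in replicate 5). LB PE was below it too (0.821 in replicate 3 and 1.004 in replicate 5). This order depended on the settings. In replicate 3 LB TE was above LB EPI at 50 CPM (1.161 against 0.9749) and with 1 set of genes (1.008 against 0.8597). So was LB PE (1.101 and 0.9491). In replicate 5 LB PE was above LB EPI at 1 CPM (0.8879 against 0.8034), while LB TE stayed below it. Exact p was 0.667 for LB PE against LB TE, 0.8 for LB TE against MB TE, 1 for LB EPI against MB ICM, 0.657 for day 9 against day 8 and 0.9 for day 9 against day 6, and the signs of these changed under some alternatives except for day 9 against day 8.

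The share of all values that came from X genes was lower in trophectoderm than in inner cells in each library holding both, 4 of 4 pairs. On day 8 it was 2.31% against 2.59% in replicate 1 and 3.03% against 3.79% in replicate 2, and on day 9 it was 2.55% against 3.11% in replicate 3 and 2.63% against 3.45% in replicate 5. The exact p was 0.2 for each day (0.533 adjusted), where the smallest possible is 0.1. The permutation moves averages freely between classes, so it ignores that TE and inner cells were paired within libraries. No paired test was run. The X share as a measure was chosen after the data were seen. Among called genes, 61.6% of the 73 X genes were lower in LB TE than in LB EPI against 44.5% of autosomal genes, and 79.3% of the 29 X genes were lower in LB PE against 43.2%. As a set, X genes passed camera in neither comparison (adjusted p = 0.242 and 0.0733, and adjusted p = 0.871 in both with an estimated correlation). From day 6 to day 7 X genes stood lower, with a median log2 change of -0.25 (camera adjusted p = 0.00308, adjusted p = 0.871 with an estimated correlation). For LB TE against LB EPI, the X inactivation list had 0 of 11 genes called by limma, over all genes or over the list alone (camera adjusted p = 0.487). Of 24 X-linked housekeeping genes 3 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.628), and of 14 genes that escape X inactivation in humans 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.329).

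XIST is the RNA that coats and silences an X chromosome, and its reads were spread unevenly over the libraries. Reads of XIST were present in 97.9% of cells in replicate 2 (95% interval 88.7 to 99.9), 85.1% in replicate 6, 56.2% in replicate 4, 31.2% in replicate 5, 22.9% in replicate 1 and 14.6% in replicate 3. Thinned to 20000 reads per cell, with 2, 8, 3, 5, 2 and 2 shallower cells left out in that order, the shares were 91.1%, 64.1%, 26.7%, 9.30%, 8.70% and 10.9%. In each library holding both classes the mean of XIST was lower in TE than in MB ICM or LB EPI, at 0.907 against 14.7 CPM in replicate 1 and 172 against 364 in replicate 2 for MB cells. For LB TE and LB EPI it was at 1.66 against 2.78 in replicate 3 and 2.28 against 2.54 in replicate 5. The last of these gaps is small, and in replicate 5 XIST reads were present in 44.4% of LB TE cells against 20.8% of LB EPI cells. No call was made by limma, where the spread between libraries was wide, with a log2 change of -1.49 (SE 1.21, adjusted p = 0.531) for MB TE against MB ICM and -0.83 (SE 1.34, adjusted p = 0.794) for LB TE against LB EPI. Neither the sex nor the embryo of a cell is labelled.

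**Figure D2:**
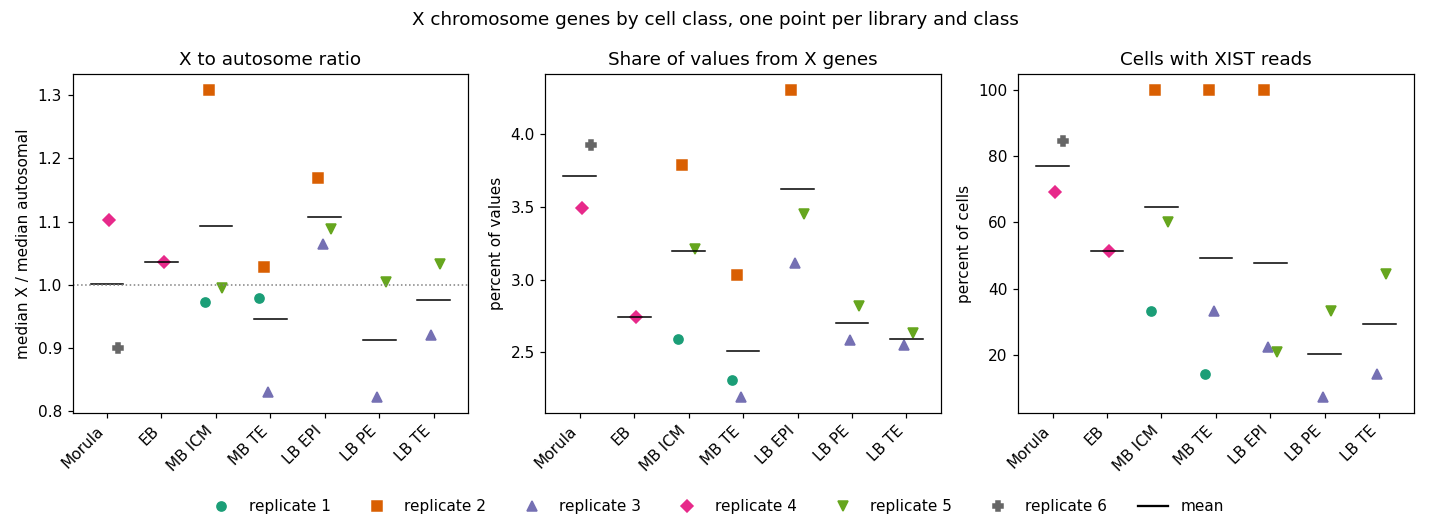
X chromosome genes by cell class. The panels give, from left to right, the ratio of median X to median autosomal expression, the percent of all values from X genes and the percent of cells with XIST reads; each point is 1 library and class, its shape and colour give the replicate, and black lines are means. In LB EPI, MB ICM and MB TE replicate 2 lies highest in all panels, with XIST reads in 100% of its cells of these classes.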

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

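The tests of cumulus cells and of sequencing depth below, the reads of BTG4 per cell and the intervals over cells were chosen only after results were seen, while the others were written down beforehand.

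The TE minus inner cell difference of 46 genes differed between day 9 and day 8 by the interaction test. The inner cells were LB EPI on day 9 and the undivided MB ICM on day 8, so an interaction is not by itself a change in TE. LRRC3, ERAS, TDGF1, ICOSLG and PPP2R2B were higher in LB EPI than in MB ICM, and CD38, MPZL2 and FOLR1 were lower. The flagged genes with a negative difference were LRRC3 (-3.913), ERAS (-3.78), TDGF1 (-3.558), ICOSLG (-3.113), GLUD1 (-2.773) and PPP2R2B (-2.587). Those with a positive difference were PHGDH (3.656), CD38 (3.392), NUPR1 (3.369), SLC6A20 (3.305), MPZL2 (2.951) and FOLR1 (2.867). None of these was called without replicate 3, where the adjusted p was 0.0562 for GLUD1 and NUPR1, 0.308 for CD38, 0.406 for ICOSLG and 0.431 for PPP2R2B. Calls were also lost for ICOSLG (adjusted p = 0.105), PPP2R2B (0.114) and NUPR1 (0.132) without replicate 1, for NUPR1 without replicate 2 (0.086), and for NUPR1 (0.0618), ICOSLG (0.0982), CD38 (0.0982) and PPP2R2B (0.11) without replicate 5. TDGF1 on day 8 had 1 library far from the others, at 3.639 on the scale log2(CPM + 10) against 5.428 to 5.715. It was 1 of 22 groups tested, and chance alone puts a library this far out in about 5% of groups.

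Morula cells of replicate 6 with few reads held oocyte transcripts at 5793 CPM in 18 cells under 50000 reads (interval over cells 2420 to 9586), against 120.3 in 17 cells of at least 200000. The signal was uneven, since 4 of the 18 cells held 388 to 732 oocyte reads each and 82.32% of the total, while the other 14 held 6 to 89, against 17 to 120 in the deep cells. Low depth alone could not be judged from other libraries. The highest level in their shallow cells was 245.5 (interval over cells 138.7 to 416.1) in replicate 5, which held no morula cells. Among the other libraries only replicate 4 held morula cells, and its shallow cells, at 97.75 CPM, were not split from EB cells. Within replicate 6 those 4 shallow cells each held more oocyte reads than any deep cell, which argues against low depth alone for them. For the other 14 low depth was not decided. For cumulus or granulosa cells, the cell highest in cumulus genes held 43830 CPM of these and 348.6 of oocyte transcripts. At that ratio the 354.7 CPM of cumulus genes in the shallow cells would bring 2.821 CPM of oocyte transcripts (upper limit 6.048). That single cell was picked by its cumulus level, which favours a low ratio, so the ratio alone does not exclude them. Cumulus genes did not follow the oocyte signal, at 349.1 CPM in the 4 high cells and 357.5 in the other 14. Free RNA shared by the wells did not account for the pooled level, since it would bring each well the same. BTG4 reads numbered 82 per shallow cell against 7.176 per deep cell (intervals over cells 25.72 to 150.6 and 4.646 to 10.24). The share of BTG4 in oocyte reads was 39.73 points higher in shallow cells, although genes such as TLE6 lower that share in deep cells. Both values pool the 18 shallow cells, and BTG4 was not split between the 4 high cells and the other 14. Those 14 had a median of 26 oocyte reads against 31 in deep cells, so shared RNA is not excluded for them. RNA brought into single wells was not tested, and no biological explanation was tested because the labels give no group within the morula cells.

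The X share of values was lower in TE than in inner cells in 4 of 4 library pairs, by 0.608 points on average (SD 0.241). Abundant trophectoderm genes may dilute all other values, and without genes above 500 CPM 52.68% of the difference was left, but this also took out 25 X genes, the 10 most abundant among them, so it does not test dilution by itself. A few abundant X genes may carry it, and without the 10 most abundant X genes 49.11% was left, with TE lower in 4 of 4 pairs either way. The latter value lies too close to the limit of 50% to decide. The removal also lowered the X share of every average, as from 2.594% to 1.447% in MB ICM of replicate 1. The gap in points would thus shrink even if the change were spread evenly. The mean difference left was -0.2985 points (SD 0.13), which argues against these 10 genes alone carrying it in these 4 pairs. Whether they or dilution carry a part cannot be told apart from a change spread over X genes. No biological explanation such as sex or X inactivation was tested, since neither is labelled.

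Replicate 2 had the highest X share of values in each of the 3 classes it shared with other libraries, and XIST reads in nearly every cell. Without XIST its X share was still above that of every other library, by at least 0.549 points. Without its 10 most abundant X genes the gap was at least 0.231 points. Thinned to 20000 reads per cell, 91.11% of its cells kept XIST reads, so depth did not account for the share of cells with XIST. Depth was not tested for the X share. Sex or embryo could differ between libraries, but neither is labelled and no biological explanation was tested.

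The library averages were also regrouped in every other way. For day 9 against day 8 the real grouping called 130 genes and was the highest of 35 groupings, with 2 genes at most in another, and 1 at most in the others of the 8 groupings, the real one included, that part as many libraries. For MB TE against MB ICM it called 1264 genes against at most 2, and for LB EPI against MB ICM 640 against at most 6. With 10 groupings each, these are too few for a test.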

How the results depend on the processing

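The library as a fixed effect, limma-voom, the removal of shallow cells and the X share were chosen after the data were seen. Of 4047 values of the genes named in the text, each under 1 alternative, 3642 kept their direction and their side of the threshold, 378 were no longer past it, 16 passed it newly and 11 changed direction. Median-of-ratios scaling moved no count of called genes by more than 1.5 times. Unless said otherwise, the cause of a difference was not tested. The few libraries limit every comparison.

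With a pseudocount of 1 the called genes numbered 0 for day 7 against day 6 (608 at an unadjusted p under 0.05), 3 for day 8 against day 7, 62 for day 9 against day 8, 4 for LB TE against MB TE and 11 for the interaction, where CDX2 turned to 0.5253. With a pseudocount of 50 they were 15 for day 7 against day 6, 43 for LB TE against MB TE and 86 for the interaction. Without a filter on low values they were 27 for day 7 against day 6, 51 for day 8 against day 7, 16 for day 9 against day 8, 428 for LB PE against LB EPI, 419 for LB EPI against MB ICM and 10 for the interaction, and GATA6 in MB TE against MB ICM turned to 0.005917. With the mean over cells of log2 values they were 12 for day 7 against day 6, 1246 for LB PE against LB TE, 86 for LB TE against MB TE, 985 for LB EPI against MB ICM and 155 for the interaction, and GATA6 in MB TE against MB ICM turned to 0.3914. With at least 5 cells per average, which leaves fewer averages, they were 1 for day 7 against day 6, 69 for day 9 against day 8, 818 for MB TE against MB ICM, 15 for LB TE against MB TE and 13 for the interaction, where KRT18 turned to 0.007563.

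Without the replicate block called genes numbered 1 for day 7 against day 6, 18 for day 9 against day 8, 387 for LB PE against LB EPI, 439 for LB PE against LB TE, 11 for LB TE against MB TE and 13 for the interaction, and GATA6 in MB TE against MB ICM turned to 0.04896. With the library as a fixed effect, also a replicate block, they were 0 for day 7 against day 6 (553 at an unadjusted p under 0.05), 0 for day 9 against day 8 (1145), 4 for LB TE against MB TE and 401 for LB EPI against MB ICM, and KRT18 in the interaction turned to 0.0329. The block moved no other count by more than 1.5 times, and no fixed effect could be fitted for steps between days that share no library.

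With limma-voom on summed recovered reads called genes numbered 41 for day 7 against day 6, 17 for day 8 against day 7, 929 for day 9 against day 8, 2223 for day 9 against day 6, 3208 for LB TE against LB EPI, 414 for LB PE against LB EPI, 84 for LB TE against MB TE, 1216 for LB EPI against MB ICM and 122 for the interaction, where CDX2 turned to 0.5671. Without cells under 20000 reads they were 0 for day 7 against day 6 (905 at an unadjusted p under 0.05), 4 for day 8 against day 7, 240 for day 9 against day 8, 818 for day 9 against day 6, 42 for LB TE against MB TE and 113 for the interaction. Without cells under 50000 reads they were 9, 351 and 1021 for day 7 against day 6, day 9 against day 8 and day 9 against day 6, 43 for LB TE against MB TE and 115 for the interaction.

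Leaving out 1 library at a time gave 0 to 3 called genes for day 7 against day 6, 0 to 9 for day 8 against day 7, 22 to 106 for day 9 against day 8, 130 to 813 for day 9 against day 6, 635 to 1260 for MB TE against MB ICM, 851 to 1882 for LB TE against LB EPI, 260 to 617 for LB PE against LB EPI, 168 to 705 for LB PE against LB TE, 3 to 27 for LB TE against MB TE, 315 to 604 for LB EPI against MB ICM and 0 to 49 for the interaction. GATA6 in MB TE against MB ICM turned to 0.4245 without replicate 2, and without replicate 3 CDX2 in LB PE against LB EPI turned to -0.182, GATA3 in LB TE against MB TE to 0.1289 and KRT18 in the interaction to 0.00472. The log2 changes over these fits ran from -0.311 to 0.4245 for that GATA6 value, from -0.182 to 0.8114 for CDX2, from -0.4125 to 0.1289 for GATA3 and from -0.5072 to 0.00472 for the last (KRT18, interaction). A class or day left with 1 average is assumed to vary like the others.

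With an estimated correlation these lists no longer passed camera. For MB TE against MB ICM they were hypoblast (adjusted p = 0.0766) and ribosomal protein (0.479), for LB TE against LB EPI lipid and sterol (0.494), ribosomal protein (0.72), FGF and ERK (0.167) and epigenetic (0.338), for LB PE against LB EPI trophectoderm (0.122) and fibroblast (0.763), and for LB PE against LB TE fibroblast (0.263). For LB TE against MB TE they were trophectoderm and ribosomal protein (0.711 each), and for LB EPI against MB ICM hypoblast (0.167), Nodal, BMP and WNT (0.0647), oxidative phosphorylation (0.348) and glycolysis (0.514). For the interaction they were trophectoderm and hypoblast (0.345 each), for day 9 against day 8 oxidative phosphorylation (0.408), and for day 9 against day 6 ribosomal protein and oocyte (0.545 each). They were oocyte (0.692) for day 7 against day 6, and trophectoderm (0.457) and epigenetic (0.125) for day 8 against day 7. With fry the adjusted p was 0.815 and 0.193 for oocyte and epigenetic genes of day 7 against day 6, 0.786 and 0.128 for trophectoderm and epigenetic genes of day 8 against day 7, 0.174 for ribosomal protein and 0.08 for lipid and sterol genes in LB TE against LB EPI, 0.368 and 0.0871 for fibroblast genes in LB PE against LB EPI and LB TE, 0.942 for both lists of LB TE against MB TE, 0.0753 for hypoblast and for oxidative phosphorylation and 0.215 for glycolysis in LB EPI against MB ICM, and 0.314 for both interaction lists. Fry also gave 0.0677, 0.0856 and 0.377 for epiblast, Nodal and oxidative phosphorylation genes of day 9 against day 8, 0.167 and 0.294 for ribosomal protein and oocyte genes of day 9 against day 6, and 0.0225, now past the threshold, for cell cycle genes in MB TE against MB ICM.

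For the X to autosome ratio, group means were compared here, not pairs within libraries. Their difference changed sign for LB PE against LB TE with a threshold of 1 CPM (0.0904). It also did so there with the mean after removing the top 5% (0.00923) and with the X share (0.112 points). It did so for LB TE against MB TE with a threshold of 1 CPM (-0.0189), for LB EPI against MB ICM with a threshold of 50 CPM (-0.00278) and 1 set of genes (-0.0347), and for day 9 against day 6 with a threshold of 50 CPM (-0.00789), 1 set of genes (-0.012) and the X share (-0.431 points). Leaving out 1 library gave -0.0835 to 0.121 for day 9 against day 6, 0.00765 to 0.0777 for day 9 against day 8, -0.0446 to 0.093 for LB EPI against MB ICM, -0.0261 to 0.0715 for LB TE against MB TE, -0.296 to -0.125 for LB PE against LB EPI, -0.0986 to -0.029 for LB PE against LB TE, -0.197 to -0.096 for LB TE against LB EPI and -0.223 to -0.0788 for MB TE against MB ICM. Among cells at or above the median number of genes, shares were 9.7902% for EB, 4.1958% for LB PE, 16.084% for LB TE, 11.189% for MB ICM and 17.483% for MB TE.

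Count models were not run, although whole reads were recovered from the deposited logarithms, and limma-voom was the only test run on those reads. Alternatives for SOX2 editing and for sex, and leaving out single embryos, were not run because those comparisons were not analysed here.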

Other observations

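Single members of the glycolysis, Hippo and stress lists differed between LB TE and LB EPI, though none of these lists passed its test. In LB TE the hexokinase HK1 was at 57.1 ± 4.27 CPM (SD, n = 2) against 226.4 ± 36.1 in LB EPI (n = 3), a log2 change of -1.86 (SE 0.29, adjusted p = 0.00011), and the mutase PGAM1 changed by -1.99 (SE 0.25, adjusted p = 1.38e-05). As a list, 3 of 18 glycolysis genes fell and 0 rose (4 and 0 adjusted over the list alone), which did not pass the test (camera adjusted p = 0.0929). Hippo pathway genes rose in 4 of 19 and fell in 2 (4 and 2 adjusted over the list alone; camera adjusted p = 0.502), among them AMOT, up by 2.10 (SE 0.37, adjusted p = 0.000455), and AMOTL1, which changed by -1.67 (adjusted p = 0.00312, but 0.0657 without replicate 5). Of 27 p53 and stress genes 3 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.628), with the autophagy receptor SQSTM1 up by 1.80 (SE 0.36, adjusted p = 0.00129) and DDIT4, an inhibitor of mTORC1, at 26.8 ± 0.298 against 280.4 ± 154 CPM (log2 change -2.87, SE 0.48, adjusted p = 0.000311). The interferon list had 0 of 10 genes called by limma, over all genes or over the list alone (camera adjusted p = 0.799).

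In LB PE against LB TE the Hippo list did not pass the test (2 of 19 up and 2 down, 2 and 3 adjusted over the list alone; camera adjusted p = 0.924), and its median log2 change, 0.14, and mean, -0.016, differed in sign. The YAP target ANKRD1 rose by 2.46 (adjusted p = 0.0208, but 0.309 without replicate 5), while AMOT changed by -1.66 (adjusted p = 0.014, but 0.177 without replicate 3 and 0.086 without replicate 5).

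In 1 morula cell of replicate 6 cumulus and granulosa genes reached 43830 CPM, and the 10 cells of its depth range held 4113 CPM together. The fibroblast list stood at 5419 CPM in cells of replicate 2 under 50000 reads, 2092 in replicate 5 and 1574 in replicate 6, against 540, 364.3 and 152.7 in cells of at least 200000 reads. The first of these rests on 4 cells. No TE cell of replicates 2 and 5 had under 50000 reads, so class and depth cannot be told apart there. The list also differed by class, with averages of 2497 CPM in LB PE and 262.9 in LB TE of replicate 5. In replicate 6 only Morula cells were pooled. In replicates 1, 3 and 4 the gaps were smaller, at 758.1 against 284.9, 574 against 498 and 533.6 against 186 CPM.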
